A study of Homo sapiens with 12 samples.

How the data were processed

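RNA from SZ95 sebocytes was measured on 12 Affymetrix HuGene 1.0 ST arrays, 3 in each of 4 groups: scramble or OLR1 siRNA, each untreated or with UV-PAPC at 25 µg/ml. Per the labels, cells grown in Sebomed medium were transfected by lipofection and treated 24 h later, and 100 ng of RNA were labelled with the WT PLUS kit. The log2 signals per probe set were made by the authors with RMA in Affymetrix Expression Console 1.3.1.187, per the submitters' processing notes, and were used as deposited. The settings of RMA, the siRNA sequences and the length of the UV-PAPC exposure are not given in the sources used here. RMA compresses large fold changes. Nothing says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

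The table held 33297 entries. Of these, 19460 carried 1 gene symbol, 1754 several and 12083 none in the probe annotation. Of the entries with 1 symbol, 19429 were matched by Entrez number to a table of current symbols, which changed 0 of them, and 31 were not matched. Its header date is older than those symbols, so the pairing of probes with genes may be old. For each gene with 1 symbol the probe set with the highest mean was kept (769 genes had more than 1), which left 18417 genes and 14880 entries not tested. Probe positions were not used. Near-identical paralogs share probe signal, which makes single members of the AKR1C, metallothionein, SPRR2, Hsp70 and histone families uncertain. List members without a tested probe set were not analysed here.

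The 4 group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual and 7.66 prior degrees of freedom), with default eBayes, two-sided moderated statistics and Benjamini-Hochberg adjustment within a comparison at a threshold of 0.05. The 5 comparisons were UV-PAPC against untreated under each siRNA, OLR1 against scramble siRNA in each treatment, and the difference of the UV-PAPC responses between siRNAs. The genes named were OLR1, the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose 3 arrays of one group all lay above the 3 of the other (small RNA genes, uncharacterised loci and antisense or readthrough genes left out), the 5 genes with the lowest p in the difference of responses, and members of the gene lists. This rule, the lists, the comparisons and the first set of alternatives were chosen before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

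The 34 gene lists came from general knowledge of stress, signalling, lipid, cell cycle and differentiation genes and of markers of other cell types, and held 958 members, of which 878 were measured (838 distinct genes). Some genes are in more than 1 list, SQSTM1 and PLIN2 among them. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison; an estimated correlation and fry, which tests whether the genes of a set move one way on balance, were the alternatives. The size of the response was tested with camera in the difference contrast, on the genes past the threshold for the average UV-PAPC effect.

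The fit was tested on simulated data with 100 changed genes of each size among 18417. In the UV-PAPC responses under scramble and OLR1 siRNA, 83% and 78% of log2 changes of 0.5 and 99% and 98% of log2 changes of 1 were recovered, with 8 and 18 false calls. For the OLR1 siRNA effects in untreated and UV-PAPC cells the shares were 91% and 81% at 0.5 and 100% and 99% at 1, with 4 and 14 false calls. For the difference of responses 37% and 97% were recovered, with 4 false calls. A list shifted by 0.2 was called by camera with both correlations and by fry, with 0 other lists called, and 0 of 40 sets were called for response size in 20 simulations without a difference. Genes were drawn independently, so correlated genes were not tested in this way.

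The alternatives were trend and robust eBayes, array weights, the genes above the median mean signal, the mean of a gene's probe sets, all table entries, arrays centred on their medians, repeated quantile normalization, the 6 arrays of a comparison alone, replicate numbers as a block and each array left out in turn. Cyclic loess between arrays, 4 arrays left out together (in each group the highest on the first component of the deviations from group means) each array left out in turn for the gene lists, the scavenger receptor list without OLR1 and the share of falls under 3 rescalings were chosen after seeing the data.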

Results

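Gene expression was measured on 12 Affymetrix whole-transcript arrays in SZ95 sebocytes, an immortalised human cell line derived from the sebaceous gland. Cells received a scramble siRNA or an siRNA against OLR1 and, 24 h later, either 25 µg/ml of PAPC oxidised with ultraviolet light (UV-PAPC) or no treatment. PAPC is a phosphatidylcholine that carries arachidonic acid, and its oxidation yields a mixture of oxidised phospholipids. OLR1 encodes LOX-1, a scavenger receptor that binds oxidised low-density lipoprotein. The 4 groups held 3 replicate arrays each, so n = 3 for every group named here. The labels name no vehicle control, no unoxidised PAPC and no untransfected cells. A response to UV-PAPC therefore means the difference from untreated cells, and effects of oxidation cannot be told apart from those of the lipid or its vehicle. The length of the exposure to UV-PAPC is not given in the sources used here. The values were log2 signals, with array medians from 5.73 to 5.83, and 18417 genes were tested. Across genes, which are not independent replicates, Pearson's r was 0.994 to 0.996 between arrays of one group and 0.989 to 0.994 between arrays of different groups. The number of arrays limits the precision. Fold changes are given on the log2 scale. For the genes opening each comparison the standard error (SE) of the limma fit and a Benjamini-Hochberg adjusted p stand beside them, and other genes said to rise or fall passed an adjusted p threshold of 0.05.

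OLR1, the gene targeted by the siRNA, was read by 1 probe set (7961142) and was lower in every OLR1 siRNA array than in every scramble array. In untreated cells its log2 signal was 6.18, 5.56 and 5.35 with scramble siRNA and 4.66, 4.38 and 4.48 with OLR1 siRNA. With UV-PAPC it was 6.19, 5.49 and 5.74 with scramble siRNA and 4.47, 4.33 and 4.41 with OLR1 siRNA. OLR1 therefore fell 2.28-fold in untreated cells (log2 fold change -1.19, 95% CI -1.57 to -0.81, limma adjusted p = 0.000484) and 2.64-fold with UV-PAPC (-1.40, 95% CI -1.78 to -1.02, adjusted p = 0.000162). Among all tested genes of an array, OLR1 lay between the 34.0th and 47.2th percentile of signal with scramble siRNA and between the 19.1th and 24.0th percentile with OLR1 siRNA. UV-PAPC gave OLR1 a log2 fold change of 0.11 (SE 0.18, adjusted p = 0.815) with scramble siRNA and -0.10 (SE 0.18, adjusted p = 0.837) with OLR1 siRNA, neither past the threshold.

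**Figure D1:**
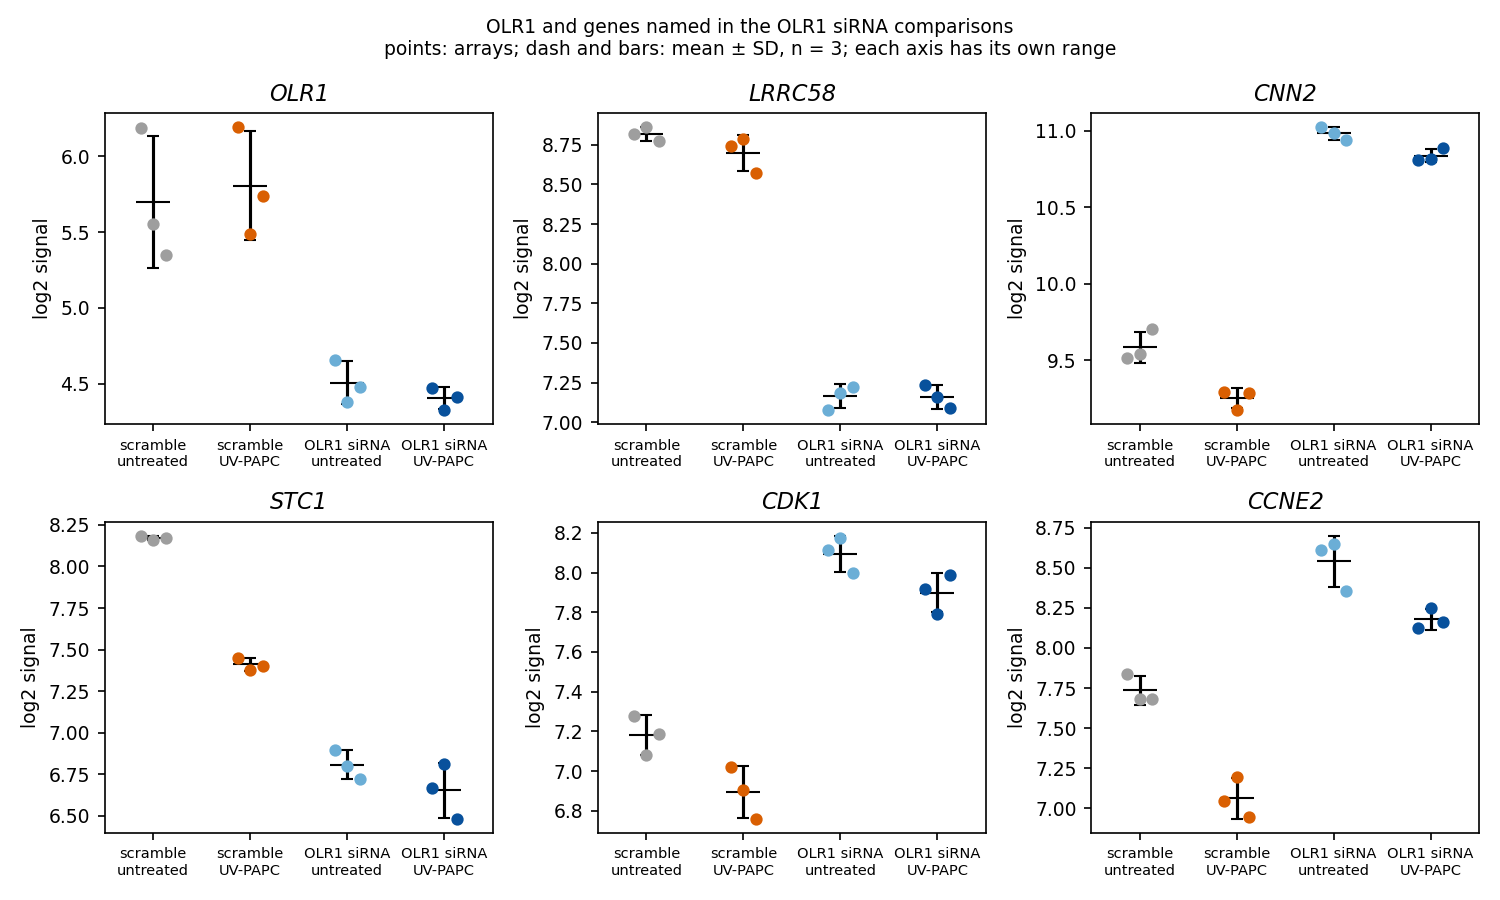
Log2 signal per array (y axis) of OLR1 and 5 genes named in the OLR1 siRNA comparisons, in the 4 groups (x axis). Points are arrays, the dash and bars are the mean ± SD (n = 3), and each panel has its own range; OLR1 lies at 4.33 to 4.66 in the 6 OLR1 siRNA arrays and at 5.35 to 6.19 in the 6 scramble arrays.

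The first comparison shows how sebocytes with scramble siRNA responded to UV-PAPC: 21 of 22 heat shock genes and 18 of 40 NRF2 targets rose, and 24 of 36 G2/M and mitosis genes fell. HSPA6, a stress-inducible Hsp70 chaperone, rose 18.3-fold (log2 fold change 4.20, SE 0.12, adjusted p = 5.87e-12). HMOX1, the heme oxygenase that degrades heme, rose 7.99-fold (3.00, SE 0.10, adjusted p = 3.05e-11), and SLC7A11, the cystine importer subunit that feeds glutathione synthesis, rose 4.59-fold (2.20, SE 0.09, adjusted p = 1.45e-10). TNFSF15, a cytokine of the TNF family, fell 2.93-fold (-1.55, SE 0.09, adjusted p = 2.27e-08), and DUSP10, a phosphatase of the stress kinases p38 and JNK, fell 2.27-fold (-1.18, SE 0.09, adjusted p = 3.4e-07).

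The other genes with the largest rises were ZFAND2A, a proteasome-associated zinc finger protein (2.88), the Hsp40 co-chaperones DNAJB1 (2.31), DNAJB4 (2.18) and DNAJA4 (1.81), the NRF2-regulated pseudogene NMRAL2P (2.55), the actin-related ACTRT3 (1.83) and the Hsp70 co-chaperone BAG3 (1.56), with SEs from 0.07 to 0.16. The other genes with the largest falls were the activin antagonist FST (-1.15), the BMP antagonist NOG (-1.13), the cytokines LIF (-1.11) and IL24 (-1.11), the osteoprotegerin gene TNFRSF11B (-1.09), the adhesion gene NECTIN4 (-1.09), the MET regulator MACC1 (-1.06) and the G protein signalling regulator RGS4 (-1.02), with SEs from 0.07 to 0.14. The rule for naming required that in each of these 20 genes all 3 UV-PAPC arrays lay on one side of all 3 untreated arrays. The largest adjusted p among them was 0.000164, for RGS4.

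Of 22 measured genes of the heat shock response, 21 rose and 1 did not pass, also when adjusted over the list alone, with a median log2 fold change of 0.64. HSPA4L (1.24), HSPH1 (1.12) and SERPINH1 (0.96) rose beside the genes above, and the small heat shock gene CRYAB was at -0.01 (SE 0.08). Near-identical Hsp70 genes can share probe signal with HSPA6, so its identity is uncertain to that extent. As a set the list was higher than other genes (camera adjusted p = 1.59e-42; adjusted p = 0.023 with an estimated correlation). Among 40 measured NRF2 targets, 18 rose and 22 did not pass (25 rose and 1 fell adjusted over the list alone). They included SRXN1, which reduces peroxiredoxins (1.34), OSGIN1 (1.13), the glutathione synthesis genes GCLC (1.15) and GCLM (0.71), and TXNRD1, a thioredoxin reductase (0.94). The set was higher (camera adjusted p = 4.81e-23; adjusted p = 0.026 with an estimated correlation).

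Of 39 measured genes of the ATF4 integrated stress response, 10 rose, over all genes and adjusted over the list alone, and 29 did not pass. CTH, of cysteine synthesis (0.70), the stress transcription factor DDIT3 (0.68) and the glutathione-degrading CHAC1 (0.58) were among the 10. The set was higher (camera adjusted p = 6.07e-05; adjusted p = 0.43 with an estimated correlation). In cholesterol synthesis SC5D alone rose (0.36) of 21 measured genes, also adjusted over the list alone; camera gave adjusted p = 0.0437, and adjusted p = 0.70 with an estimated correlation. The median of 0.0684 was 0.106 after repeated quantile normalization and 0.111 after cyclic loess, chosen after seeing the data. Of 11 metallothionein and metal response genes 5 fell and 6 did not pass, also adjusted over the list alone, among them MT2A (-0.25), MT1X (-0.39) and the zinc exporter SLC30A1 (-0.33). The metallothioneins are near-identical, so their separate values are uncertain, and the set's camera adjusted p = 0.00111 became adjusted p = 0.29 with an estimated correlation.

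Of 36 measured G2/M and mitosis genes, 24 fell and 12 did not pass (29 fell adjusted over the list alone), with a median of -0.35. TOP2A, which untangles DNA (-0.84), the mitotic cyclin CCNB1 (-0.72), the kinesin KIF23 (-0.71) and the kinase PLK1 (-0.66) were among them (camera adjusted p = 3.46e-24; adjusted p = 0.069 with an estimated correlation). In the list of G1/S and DNA replication genes 5 of 35 fell and 30 did not pass (10 fell adjusted over the list alone), including the cyclin CCNE2 (-0.67) and the checkpoint gene CLSPN (-0.37). That list had camera adjusted p = 2.65e-05, and adjusted p = 0.29 with an estimated correlation.

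Of 27 inflammatory cytokines and chemokines 6 fell and 21 did not pass (1 rose and 6 fell adjusted over the list alone). Besides TNFSF15, LIF and IL24 these were IL1B (-0.79), IL1A (-0.64) and the interleukin-1 receptor antagonist IL1RN (-0.43), and the set had camera adjusted p = 0.00075, and adjusted p = 0.10 with an estimated correlation. Of 26 NF-kB pathway targets 7 fell, 2 rose and 17 did not pass (10 fell and 4 rose adjusted over the list alone). The inhibitors of the pathway TNFAIP3 (-0.93) and NFKBIA (-0.52) and the urokinase gene PLAU (-0.77) fell, and the RNase gene ZC3H12A (0.37) and serum amyloid SAA1 (0.47) rose. The set had camera adjusted p = 0.00075, and adjusted p = 0.10 with an estimated correlation. Of 37 interferon-stimulated genes 11 fell and 26 did not pass (13 fell adjusted over the list alone), led by IFIT2 (-1.01), IFIT3 (-0.89), SAMD9 (-0.71) and the RNA sensor RIGI (-0.70), with camera adjusted p = 1.06e-06 and adjusted p = 0.16 with an estimated correlation. Of 31 immediate early and MAPK feedback genes 11 fell, 2 rose and 18 did not pass (14 fell and 2 rose adjusted over the list alone). The transcription factors KLF6 (-0.87) and JUNB (-0.75) fell and the phosphatase DUSP1 (0.95) and IER5 (0.35) rose. The set was lower (camera adjusted p = 6.07e-05; adjusted p = 0.22 with an estimated correlation).

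Of 21 basal and simple epithelial keratin and adhesion genes 5 fell and 16 did not pass (8 fell adjusted over the list alone), among them KRT15 (-0.46), ITGA2 (-0.35) and E-cadherin CDH1 (-0.24). That set had camera adjusted p = 0.000431, and adjusted p = 0.29 with an estimated correlation. Several lists that did not pass camera held single changes. Among 24 scavenger and oxidized-lipid receptors TLR4 (0.80) and PTGER2 (0.40) rose, TLR6 fell (-0.68) and 21 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.579). Of 25 sebocyte differentiation markers the lipid droplet gene PLIN2 (0.58) and the elongase ELOVL5 (0.39) rose, the adipogenic receptor PPARG (-0.47) and PRDM1 (-0.40) fell, and 21 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.538). Growth factors went both ways: PGF (1.32) and BMP4 (0.85) were among 5 of 26 that rose, and EREG (-0.48) and PDGFB (-0.55) among 5 that fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.75). Of the lists for other cell types, 2 of 19 fibroblast markers rose, ZEB2 (0.43) and COL6A2 (0.24), and 1 of 9 melanocyte markers fell, MITF (-0.23), with 3 rises in the first and 1 rise and 2 falls in the second adjusted over the list alone. No leukocyte marker (0 of 13) and no endothelial marker (0 of 10) passed, and none of these 4 sets passed camera (adjusted p = 0.0519, 0.348, 0.415 and 0.538). Fry, which does not compare a set with other genes, gave adjusted p = 0.00822 for fibroblast and 0.0218 for melanocyte markers, both higher on balance.

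In all, limma called 1347 genes in this comparison at an adjusted p threshold of 0.05, of which 492 rose and 855 fell. At least 2-fold changes numbered 24 rises and 11 falls. The groups did not overlap in 24.1% of genes, against 10% by chance. Without the first scramble untreated array the count was 868, and with 4 arrays left out, 1 per group, an alternative chosen after seeing the data, it was 752. With each array left out in turn 346 to 470 genes rose and 512 to 770 fell; without the third scramble UV-PAPC array 470 rose and 522 fell, and with array weights 806 rose and 1036 fell. Falls outnumbered rises in every alternative run. Of 34 gene lists 12 passed with the preset correlation, and 2 of them, heat shock and NRF2, with an estimated correlation.

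**Figure D2:**
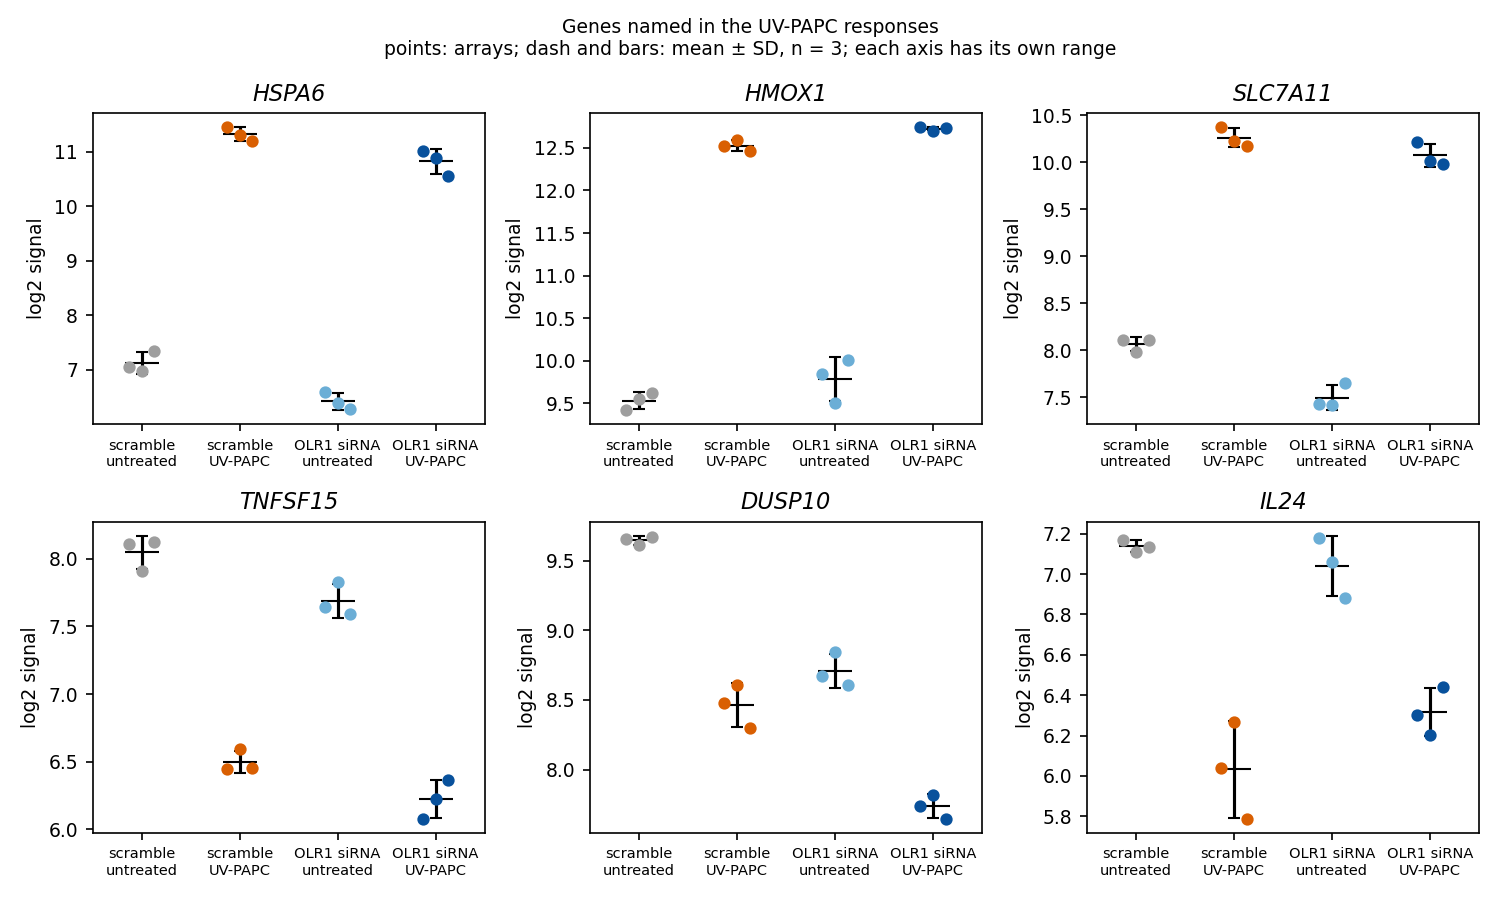
Log2 signal per array (y axis) of 6 genes named in the UV-PAPC responses, in the 4 groups (x axis). Points are arrays, the dash and bars are the mean ± SD (n = 3), and each panel has its own range; HSPA6, HMOX1 and SLC7A11 lie higher and TNFSF15, DUSP10 and IL24 lower with UV-PAPC under both siRNAs.

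The second comparison is the response to UV-PAPC in cells with OLR1 siRNA. The same kinds of genes led it: HSPA6 rose 21.1-fold (log2 fold change 4.40, SE 0.12, adjusted p = 2.86e-12), HMOX1 7.67-fold (2.94, SE 0.10, adjusted p = 2.07e-11) and SLC7A11 5.98-fold (2.58, SE 0.09, adjusted p = 1.68e-11). TNFSF15 fell 2.76-fold (-1.47, SE 0.09, adjusted p = 4.52e-08) and the epithelial transcription factor GRHL3 fell 2.06-fold (-1.04, SE 0.08, adjusted p = 3.5e-07). Further large rises were those of NMRAL2P (2.96), ZFAND2A (2.69), DNAJB1 (2.35), DNAJB4 (2.25), the arrestin-domain gene ARRDC3 (1.96), DNAJA4 (1.94) and SRXN1 (1.56), with SEs from 0.07 to 0.15. Further large falls were those of MACC1 (-0.997), DUSP10 (-0.97), the cytochrome CYP1B1 (-0.95), NECTIN4 (-0.94), the epithelial transcription factor ELF3 (-0.91), FST (-0.87), the glycosyltransferase GALNT5 (-0.87) and the cytoskeletal linker GAS2L3 (-0.86), with SEs from 0.07 to 0.14. As the rule for naming required, all 3 UV-PAPC arrays lay on one side of all 3 untreated arrays in each of these genes.

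Of the 22 heat shock genes 21 rose and 1 did not pass, also adjusted over the list alone (median 0.74; camera adjusted p = 3.25e-49; adjusted p = 0.007 with an estimated correlation). The exception was again CRYAB (-0.10, SE 0.08). HSPA4L (1.45), HSPB8 (1.28), HSPH1 (1.15) and CACYBP (1.03) were among the rises. Among 40 NRF2 targets 22 rose, SLC6A9 fell (-0.29) and 17 did not pass (28 rose and 2 fell adjusted over the list alone), including GCLC (1.36), OSGIN1 (1.17), TXNRD1 (0.95), GCLM (0.95) and NQO1 (0.37). The median was 0.36 (camera adjusted p = 7.34e-35; adjusted p = 0.007 with an estimated correlation). Of 36 G2/M genes 24 fell and 12 did not pass (32 fell adjusted over the list alone), among them TOP2A (-0.65), AURKA (-0.61), CCNB1 (-0.59) and PLK1 (-0.62), and this set too held (median -0.38; camera adjusted p = 1.32e-28; adjusted p = 0.044 with an estimated correlation). In G1/S only CLSPN (-0.31), E2F2 (-0.30) and CCNE2 (-0.36) of 35 fell, also adjusted over the list alone, with camera adjusted p = 0.0181 and adjusted p = 0.61 with an estimated correlation.

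A further 6 lists were higher with the preset correlation. Of 21 cholesterol synthesis genes 5 rose and 16 did not pass (9 rose adjusted over the list alone): SC5D (0.58), MSMO1 (0.40), GGPS1 (0.35), IDI1 (0.32) and HMGCS1 (0.29); camera gave adjusted p = 1.14e-05, and adjusted p = 0.28 with an estimated correlation. In hypoxia and glycolysis 7 of 28 rose, including the peptide hormone gene ADM (1.13) and the collagen hydroxylase P4HA2 (0.70), HK2 fell (-0.35) and 20 did not pass (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000235; adjusted p = 0.28 with an estimated correlation). Its median of 0.0769 was 0.0506 after repeated quantile normalization. Of 36 autophagy and lysosome genes 5 rose and 31 did not pass, also adjusted over the list alone: GABARAPL1 (1.13), SQSTM1 (0.74), MAP1LC3B (0.40), ATG12 (0.34) and the cathepsin CTSL (0.29); camera gave adjusted p = 0.0013, and adjusted p = 0.53 with an estimated correlation. The ATF4 list had 5 rises among 39 and 34 that did not pass (7 rose and 1 fell adjusted over the list alone), with SLC3A2 (0.57), PPP1R15A (0.52) and CTH (0.47), camera adjusted p = 0.007, and adjusted p = 0.61 with an estimated correlation. Its median of 0.00799 was 0.019 with centred arrays and 0.0148 after cyclic loess, chosen after seeing the data. HERPUD1 (0.55) and DNAJB9 (0.44) rose of 27 endoplasmic reticulum chaperones and XBP1 targets, also adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.61 with an estimated correlation). No gene of 26 in oxidative phosphorylation passed over all genes or adjusted over the list alone, with a median of 0.06, camera adjusted p = 0.0411 and adjusted p = 0.61 with an estimated correlation.

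Another 6 lists were lower with the preset correlation. Of 37 interferon-stimulated genes 10 fell and 27 did not pass (14 fell and 1 rose adjusted over the list alone), led by IFIT3 (-0.78), SAMD9 (-0.65) and SAMD9L (-0.65), with camera adjusted p = 2.96e-05 and adjusted p = 0.28 with an estimated correlation. Of 31 immediate early genes 11 fell, among them KLF6 (-0.74), PHLDA1 (-0.68) and JUNB (-0.64), DUSP1 (1.10), JUN (0.53) and IER5 (0.33) rose, and 17 did not pass (13 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.31 with an estimated correlation). NF-kB targets fell in 8 of 26, including BCL3 (-0.69), PLAU (-0.64) and TNFAIP3 (-0.58), ZC3H12A rose (0.29) and 17 did not pass (9 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.12 with an estimated correlation). Cytokines fell in 5 of 27, TNFSF15 with LIF (-0.76), IL24 (-0.72), IL1B (-0.43) and IL1RN (-0.34), and 22 did not pass (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0326; adjusted p = 0.28 with an estimated correlation). KRT15 fell (-0.45) alone of 21 keratin and adhesion genes (4 fell adjusted over the list alone; camera adjusted p = 0.0166; adjusted p = 0.55 with an estimated correlation). GRHL3, the lipid transporter ABCA12 (-0.65), GRHL1 (-0.31) and KRT80 (-0.26) fell of 35 cornified differentiation genes, also adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.28 with an estimated correlation). Among lists that did not pass camera, TLR4 rose (0.79) alone of 24 scavenger receptors, and of 25 sebocyte markers PLIN2 (0.67) and ELOVL5 (0.42) rose and PPARG (-0.35) and MUC1 (-0.34) fell; adjusted over the list alone the counts were 1 rise, and 3 rises with 3 falls (camera adjusted p = 0.943 and 0.702). None of the fibroblast, melanocyte, leukocyte and endothelial markers passed, and camera gave those sets adjusted p = 0.811, 0.692, 0.495 and 0.272; fry gave endothelial markers adjusted p = 0.0481, lower on balance.

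Limma called 1236 genes in this comparison, 638 that rose and 598 that fell, and at least 2-fold changes numbered 33 rises and 3 falls. With each array left out in turn 422 to 577 genes rose and 390 to 517 fell. Which direction held more genes was not stable: 422 rose and 449 fell without the first OLR1 siRNA UV-PAPC array, and 699 rose and 480 fell over all table entries. The groups did not overlap in 23.7% of genes, against 10% by chance. Of 34 lists 16 passed with the preset correlation, and 3, heat shock, NRF2 and G2/M, with an estimated correlation. Across genes, which are not independent replicates, the log2 fold changes of the responses under the 2 siRNAs had Pearson's r of 0.707 and Spearman's rho of 0.475. Both responses shared 348 rising genes, where independent lists would share 17.0, and 415 falling genes, where independent lists would share 27.8. In opposite directions 0 genes passed. Both tests used the same spread estimate for each gene. This alone favours shared calls, so the numbers for independent lists may be too low.

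**Figure D3:**
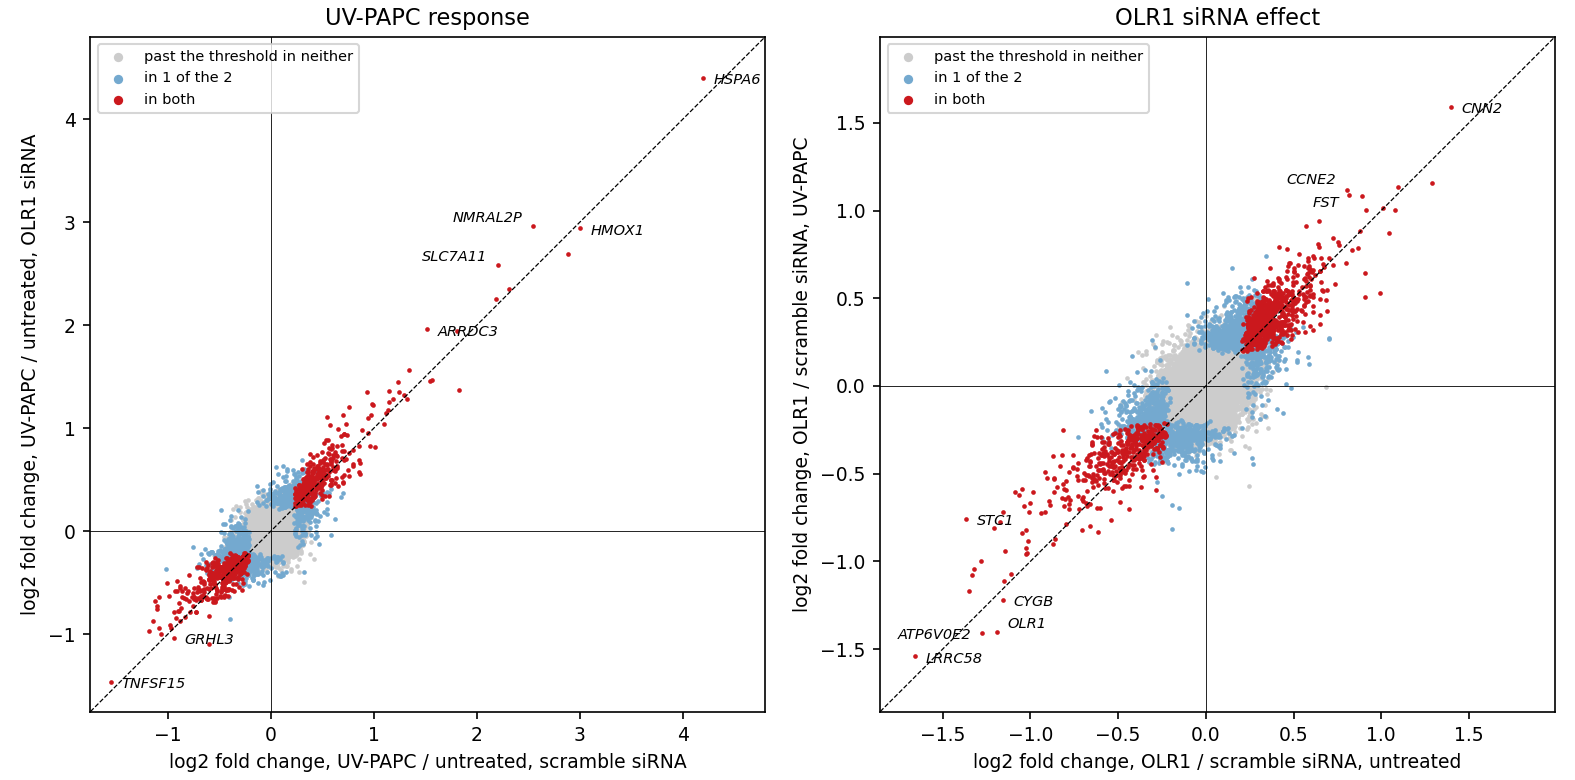
Log2 fold change of each of 18417 genes. Left, UV-PAPC against untreated with scramble siRNA (x axis) and OLR1 siRNA (y axis); right, OLR1 against scramble siRNA in untreated cells (x axis) and with UV-PAPC (y axis). Colours show genes past the adjusted p threshold of 0.05 in neither, 1 or both comparisons, and the dashed line marks equal change; 0 genes passed in opposite directions in either panel.

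The third comparison asks what OLR1 siRNA changed in untreated cells. Of the mitosis list 30 of 36 genes rose, and of the DNA replication list 17 of 35. CNN2, the actin-binding calponin 2, rose 2.64-fold (log2 fold change 1.40, SE 0.07, adjusted p = 1.1e-08), the chromatin protein HMGB2 rose by 1.29 (SE 0.08, adjusted p = 7.07e-08) and the mitotic kinesin KIF20A by 1.09 (SE 0.10, adjusted p = 6.16e-06). LRRC58 fell 3.15-fold (-1.66, SE 0.07, adjusted p = 4.77e-09) and STC1, the secreted hormone stanniocalcin 1, fell 2.58-fold (-1.37, SE 0.08, adjusted p = 7.07e-08). The other large rises were those of the hyaluronan receptor HMMR (1.08), the mRNA decapping gene DCP1A (1.04), the RNA cap methylase TGS1 (1.01), GAS2L3 (1.00), the mitotic kinase CDK1 (0.91), the kinesin KIF14 (0.91) and the cornified envelope gene SPRR2A (0.91), which has near-identical paralogs and is uncertain to that extent, with SEs from 0.07 to 0.14. The other large falls were those of the mitotic kinase NEK7 (-1.35), the mitochondrial folate carrier SLC25A32 (-1.33), the integrin ITGB6 (-1.32), the Hippo pathway gene MOB1B (-1.28), the proton pump subunit ATP6V0E2 (-1.28), the kinesin KIF3A (-1.17) and the nucleotide sugar transporter SLC35D1 (-1.16), with SEs from 0.08 to 0.11. OLR1 itself (-1.19, SE 0.18) ranked among these, and 8 genes fell at least as far as it did. With each array left out in turn OLR1 ranged from -1.365 to -0.946, so that count is uncertain. Each of the genes named here had all 3 arrays of one siRNA on one side of all 3 of the other, as the rule for naming required.

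Of 36 G2/M genes 30 rose and 6 did not pass (34 rose adjusted over the list alone), with a median of 0.57. TOP2A (0.89), CCNB2 (0.80), CENPE (0.69) and the proliferation marker MKI67 (0.66) were among them (camera adjusted p = 2.74e-40; adjusted p = 0.046 with an estimated correlation). Of 35 G1/S and DNA replication genes 17 rose and 18 did not pass (24 rose adjusted over the list alone), including CCNE2 (0.80), CLSPN (0.75), the thymidylate synthase TYMS (0.43) and the helicase subunit MCM6 (0.40), with camera adjusted p = 3.56e-15 and adjusted p = 0.13 with an estimated correlation. Immediate early and MAPK feedback genes fell in 8 of 31 and 23 did not pass (12 fell adjusted over the list alone): DUSP10 (-0.94), PHLDA1 (-0.66), DUSP6 (-0.56) and KLF6 (-0.45) led (camera adjusted p = 0.00012; adjusted p = 0.34 with an estimated correlation). IL1B (-0.76), IL1A (-0.59), TNFSF15 (-0.36) and CSF3 (-0.35) fell of 27 cytokines (5 fell adjusted over the list alone; camera adjusted p = 0.00502; adjusted p = 0.23 with an estimated correlation). HSD3B1, a steroid synthesis enzyme, fell (-0.80) alone of 25 sebocyte differentiation markers, and COX5B, of cytochrome c oxidase, rose (0.25) alone of 26 oxidative phosphorylation genes, both counts also adjusted over the list alone. Each of these 2 sets had camera adjusted p = 0.0351, with adjusted p = 0.34 and 0.80 with an estimated correlation. The oxidative phosphorylation median of 0.0826 was 0.0493 after repeated quantile normalization and 0.0396 after cyclic loess, chosen after seeing the data.

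Lists that did not pass camera also held changes. Besides OLR1, TLR4 (-0.66), PTGER2 (-0.28) and SCARB1 (-0.24) fell and CD68 (0.40) rose of 24 scavenger receptors (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.114). Without OLR1, left out after seeing the data because the siRNA targets it, the other 23 members had a mean of -0.07 (camera adjusted p = 0.284, fry adjusted p = 0.0106), lower in all 3 OLR1 siRNA arrays than in all 3 scramble arrays. In fatty acid synthesis ACSL1 (-1.01), ELOVL7 (-0.86), ACSL4 (-0.63) and ACSS2 (-0.28) fell of 31 genes, also adjusted over the list alone (camera adjusted p = 0.365). The EGF receptor ligands EPGN (-1.14) and EREG (-0.65) were among 5 of 26 growth factors that fell, and TGFA (0.58) alone rose (8 fell and 5 rose adjusted over the list alone; camera adjusted p = 0.719). Heat shock genes fell in 4 of 22, HSPA6 (-0.70), CACYBP (-0.55), FKBP4 (-0.35) and DNAJB1 (-0.34), with 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0555). Of the markers of other cell types MITF (0.26), of the melanocyte list, and CDH5 (0.65), of the endothelial list, rose, the same counts as adjusted over the list alone, and camera gave the fibroblast, melanocyte, leukocyte and endothelial lists adjusted p = 0.86, 0.915, 0.882 and 0.91.

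Limma called 1789 genes in this comparison, 975 that rose and 814 that fell; at least 2-fold changes numbered 6 rises and 27 falls. The groups did not overlap in 28.7% of genes, against 10% by chance, and 6 of 34 lists passed, 1 of them, G2/M, with an estimated correlation. The count was 1113 or 1158 without the second or the third scramble untreated array, 1101 without the second OLR1 siRNA untreated array, and 1091 with 4 arrays left out, an alternative chosen after seeing the data. Which direction held more genes was not stable: 528 rose and 585 fell without the second scramble untreated array, 536 rose and 565 fell without the second OLR1 siRNA untreated array, and 606 rose and 610 fell without the first. The share that rose was 54.5% as deposited, 62.1% with arrays centred on their medians, 52.9% after repeated quantile normalization and 51.1% after cyclic loess, also chosen after seeing the data.

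The fourth comparison asks the same of cells given UV-PAPC. CNN2 rose 3.01-fold (log2 fold change 1.59, SE 0.07, adjusted p = 3.2e-09) and CCNE2, a G1/S cyclin, 2.17-fold (1.12, SE 0.09, adjusted p = 2.13e-06). LRRC58 fell 2.91-fold (-1.54, SE 0.07, adjusted p = 7.13e-09), ATP6V0E2 2.66-fold (-1.41, SE 0.11, adjusted p = 2.23e-06) and CYGB, the globin cytoglobin, 2.33-fold (-1.22, SE 0.07, adjusted p = 5.32e-08). The other large rises were those of HMGB2 (1.16), KIF20A (1.14), FST (1.09), TOP2A (1.09), TGS1 (1.01), CDK1 (1.01), HMMR (1.00) and the semaphorin SEMA3B (0.91), with SEs from 0.07 to 0.12. The other large falls were those of NEK7 (-1.17), the phosphatase subunit ANKRD52 (-1.11), SLC25A32 (-1.08), the tight junction gene CLDN1 (-1.07), ITGB6 (-1.04) and MOB1B (-0.998), with SEs from 0.07 to 0.10. Of all genes, LRRC58 and ATP6V0E2 fell further than OLR1 (-1.40, SE 0.18). The gap between ATP6V0E2 and OLR1 was far smaller than the SE of either. With each array left out in turn OLR1 ranged from -1.56 to -1.21, so this order is not resolved. Each of the genes named here had all 3 arrays of one siRNA on one side of all 3 of the other, as the rule for naming required.

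Of 36 G2/M genes 32 rose and 4 did not pass, also adjusted over the list alone, with a median of 0.52, among them KIF23 (0.81), CCNB2 (0.70), CCNB1 (0.69) and MKI67 (0.59). The set had camera adjusted p = 4.16e-33, and adjusted p = 0.078 with an estimated correlation. Of 35 G1/S genes 23 rose and 12 did not pass (28 rose adjusted over the list alone), including CLSPN (0.82), the polymerase clamp PCNA (0.47), MCM6 (0.45) and TYMS (0.45), with camera adjusted p = 2.65e-18 and adjusted p = 0.078 with an estimated correlation. The median of 0.284 was 0.194 after repeated quantile normalization and 0.177 after cyclic loess between arrays, the latter chosen after seeing the data. In oxidative phosphorylation COX7B (0.74), COX7A2 (0.44), COX5B (0.32), NDUFA9 (0.25) and SDHD (0.19) rose of 26 genes (7 rose adjusted over the list alone; camera adjusted p = 2.4e-05; adjusted p = 0.43 with an estimated correlation). The median of 0.138 was 0.06 after repeated quantile normalization and 0.0556 after cyclic loess. Of 31 immediate early genes 6 fell, among them PHLDA1 (-0.80), DUSP10 (-0.73) and KLF10 (-0.44), SPRY2 rose (0.36) and 24 did not pass (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00634; adjusted p = 0.75 with an estimated correlation). The median of -0.0862 was -0.0542 with centred arrays, -0.148 after repeated quantile normalization and -0.149 after cyclic loess. No ribosomal protein gene of 30 passed over all genes or adjusted over the list alone, with a median of 0.10 and camera adjusted p = 0.00182; the adjusted p was 0.75 with an estimated correlation, after repeated quantile normalization the median was 0.015, and after cyclic loess -0.00109 (camera adjusted p = 0.779).

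Lists that did not pass camera again held changes. TLR4 (-0.67), PTGER2 (-0.52) and SCARA3 (-0.34) fell with OLR1, and CD68 (0.44) rose, of 24 scavenger receptors (5 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.118). Without OLR1, left out after seeing the data, the other 23 members had a mean of -0.08 (camera adjusted p = 0.247, fry adjusted p = 0.00341), again lower in all 3 OLR1 siRNA arrays. NRF2 targets rose in 7 of 40, including GCLC (0.54), the export pump ABCC2 (0.51) and GCLM (0.32), and CES1 fell (-0.41), the same counts as adjusted over the list alone (camera adjusted p = 0.0805). CHAC1 (-0.81), DDIT4 (-0.46) and TRIB3 (-0.38) were among 5 of 39 ATF4 genes that fell and MTHFD2 (0.33) alone rose (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.241). Of the markers of other cell types MITF (0.43) and CDH5 (0.50) rose and COL6A2 (-0.21) and CD8A (-0.29) fell. Adjusted over the list alone 0 fibroblast genes, 1 rise and 3 falls of melanocyte genes, 1 leukocyte fall and 1 endothelial rise passed. Camera gave the fibroblast, melanocyte, leukocyte and endothelial lists adjusted p = 0.325, 0.283, 0.32 and 0.956, and fry gave fibroblast and melanocyte markers adjusted p = 0.0465 and 0.00802, both lower on balance.

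Limma called 2302 genes in this comparison, 1462 that rose (63.5%) and 840 that fell; at least 2-fold changes numbered 9 rises and 9 falls. The share that rose was 75.5% with arrays centred on their medians, 55.2% after repeated quantile normalization and 55.5% after cyclic loess, the last chosen after seeing the data. The groups did not overlap in 30.8% of genes, against 10% by chance, and 5 of 34 lists passed, 0 of them with an estimated correlation. The count was 1372 without the third scramble UV-PAPC array, 1267 without the first OLR1 siRNA UV-PAPC array and 1161 with 4 arrays left out, an alternative chosen after seeing the data. With each array left out in turn 769 to 1437 genes rose and 498 to 863 fell, and rises outnumbered falls in every alternative run. Across genes, which are not independent replicates, the siRNA effects in untreated and UV-PAPC cells had Pearson's r of 0.718 and Spearman's rho of 0.617. They shared 723 rising genes (77.4 expected of independent lists) and 429 falling genes (37.1 expected), and 0 genes passed in opposite directions. The spread estimate of a gene was again the same in both tests, so the expected numbers may be too low.

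**Figure D4:**
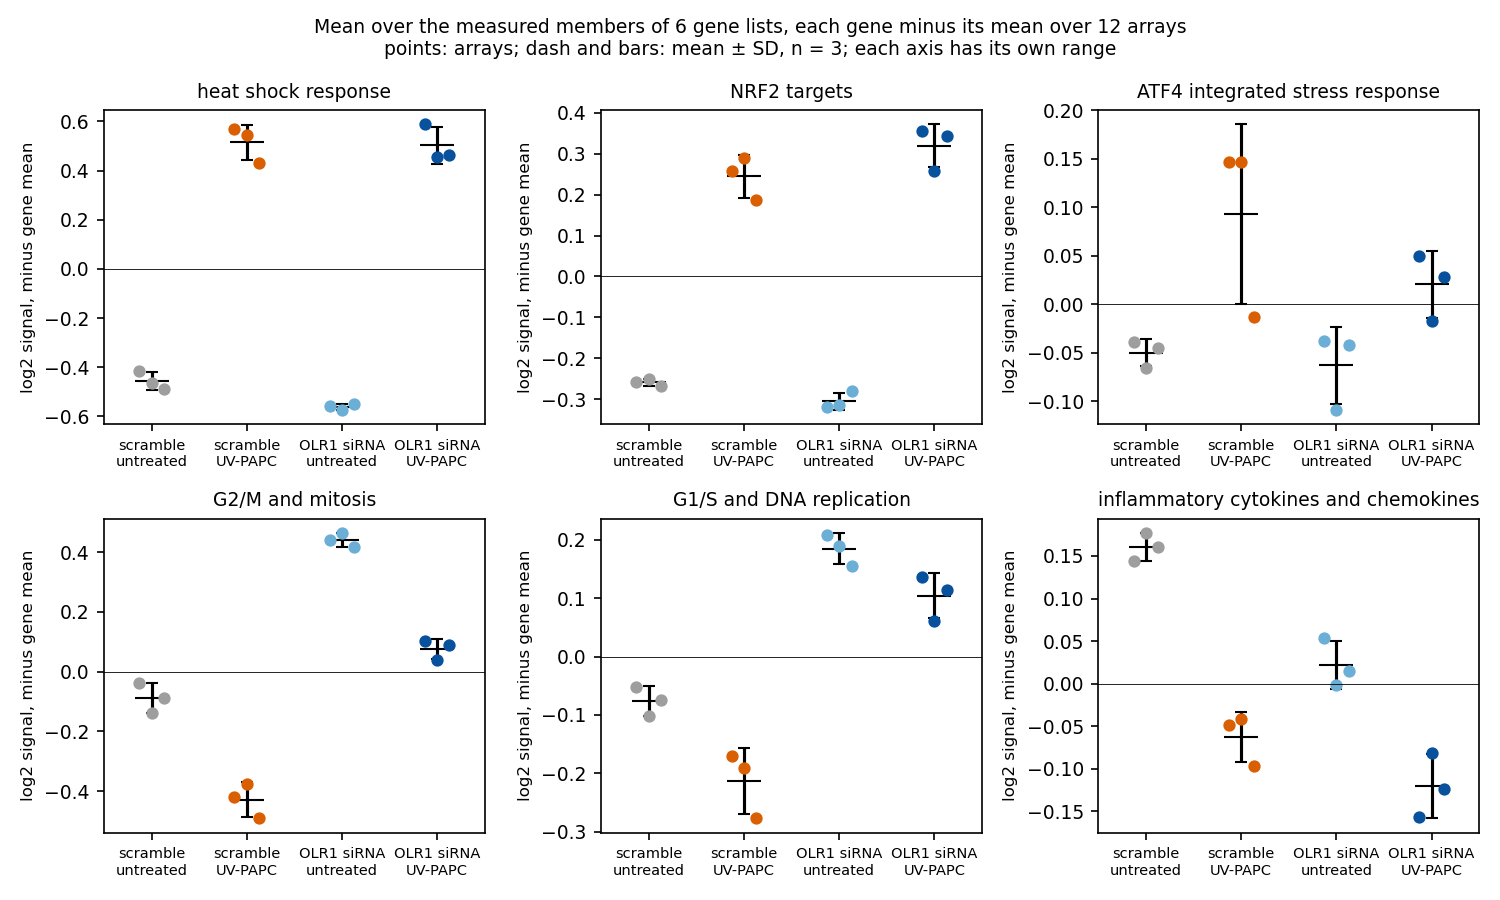
Mean log2 signal over the measured members of 6 gene lists per array, each gene taken relative to its mean over the 12 arrays (y axis), in the 4 groups (x axis). Points are arrays, the dash and bars are the mean ± SD (n = 3), and each panel has its own range; heat shock and NRF2 lists lie higher with UV-PAPC under both siRNAs, and the G2/M list lies higher with OLR1 siRNA and lower with UV-PAPC.

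The last comparison asks whether the response to UV-PAPC depended on the siRNA. The 5 genes with the lowest p for a difference were STC1 (difference of log2 fold changes 0.61, SE 0.11), the cathepsin CTSO (0.53, SE 0.10), MLLT11 (0.56, SE 0.11), the histone mRNA processing gene LSM11 (-0.53, SE 0.11) and the mitochondrial peptidase subunit IMMP1L (0.42, SE 0.09), and none of them passed (limma adjusted p = 0.52 for each). HSPA6 differed by 0.20 (SE 0.17), SLC7A11 by 0.38 (SE 0.12) and NMRAL2P by 0.41 (SE 0.14), with adjusted p = 0.931, 0.882 and 0.882. Limma called 0 genes at the threshold, with 1004 at an unadjusted p under 0.05, and 0 genes with each alternative run: trend and robust eBayes, array weights, the brighter genes alone, all table entries, mean probe sets, 3 rescalings, 4 arrays left out together and every array left out in turn. The SE of a difference was larger than that of a pairwise change, with a median of 0.116 against 0.0818.

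As sets, 6 lists had a more positive response with OLR1 siRNA at the preset correlation, with 0 members of each past the threshold over all genes. A more positive response need not mean a higher level with UV-PAPC. Mean heat shock signal, relative to gene means, was -0.57 to -0.55 in untreated OLR1 siRNA arrays and -0.49 to -0.42 in untreated scramble arrays. With UV-PAPC these arrays overlapped, at 0.46 to 0.59 and 0.43 to 0.57. Cholesterol synthesis arrays overlapped between siRNAs in both treatments. NRF2 targets had a median difference of 0.14 (camera adjusted p = 1.05e-05; adjusted p = 0.52 with an estimated correlation) and hypoxia and glycolysis genes of 0.11 (camera adjusted p = 0.000289; adjusted p = 0.52 with an estimated correlation). Heat shock genes had 0.10 (camera adjusted p = 0.0134), cholesterol synthesis 0.09 (0.0188) and oxidative phosphorylation 0.06 (0.0193), each with adjusted p = 0.69 with an estimated correlation. Fatty acid synthesis had 0.06 (camera adjusted p = 0.0183; adjusted p = 0.66 with an estimated correlation). After repeated quantile normalization and after cyclic loess, the latter chosen after seeing the data, the medians were 0.0497 and 0.0404 for heat shock genes, 0.0477 and 0.0494 for cholesterol synthesis and 0.013 and 0.012 for oxidative phosphorylation. For hypoxia and glycolysis they were 0.0684 and 0.079, for NRF2 targets 0.101 and 0.0973, and for fatty acid synthesis 0.0525 and 0.0551. Adjusted over the list alone, 1 heat shock gene, CACYBP (0.46), passed, and 0 members of the other 5 lists did. Of the 6 lists 0 passed with an estimated correlation and 0 with fry. The number of lists was 2 without the first scramble untreated array, 3 without the third scramble UV-PAPC array, 3 without the first OLR1 siRNA UV-PAPC array and 10 without the first OLR1 siRNA untreated array. Camera gave adjusted p = 0.0556 for fibroblast, 0.119 for melanocyte, 0.072 for leukocyte and 0.549 for endothelial markers, with median differences of -0.10, -0.09, -0.09 and -0.03.

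The size of the response was also compared over all responding genes. The 1096 genes that rose on average over both siRNAs, among them HSPA6 and HMOX1, had a median log2 fold change of 0.26 with scramble siRNA and 0.31 with OLR1 siRNA, a median difference of 0.05 (limma's camera p = 0.000178; p = 0.30 with an estimated correlation). The 1478 genes that fell on average, among them TNFSF15 and DUSP10, had medians of -0.28 and -0.24, also a difference of 0.05 (limma's camera p = 0.000628; p = 0.38 with an estimated correlation). Both differences were upward, so with OLR1 siRNA the median rise was larger and the median fall smaller. Without the third scramble UV-PAPC array the difference for rising genes was 0.014 and no longer passed camera, and for falling genes it was 0.0175 and passed. For falling genes it was 0.0229 without the third OLR1 siRNA untreated array and 0.0233 without the third OLR1 siRNA UV-PAPC array, and passed camera in neither. For rising genes it was 0.0271 without the first OLR1 siRNA UV-PAPC array and 0.0844 without the second, and for falling genes 0.0759 without the second scramble untreated array and 0.079 without the second scramble UV-PAPC array. With array weights it was 0.0261 for rising and 0.0296 for falling genes, and passed camera in both. Among the brighter genes alone it did not pass camera in either set, and after cyclic loess, chosen after seeing the data, it was 0.0275 for rising genes, which passed, and 0.0264 for falling genes, which did not.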

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

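The counts of other splits of the arrays were planned before their results were seen; the tests of cyclic loess, of leaving out the third scramble UV-PAPC array and of the estimated correlation as explanations were chosen only after the list result was seen.

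The response to UV-PAPC differed between siRNAs in 6 gene lists when the difference itself was tested with camera at the preset correlation, with median differences (log2, OLR1 minus scramble siRNA) of 0.142 for NRF2 targets, 0.114 for hypoxia and glycolysis, 0.0964 for heat shock, 0.0929 for cholesterol synthesis, 0.064 for fatty acid, wax ester and triglyceride synthesis and 0.0582 for oxidative phosphorylation. Genes of a list varying together between replicates may account for these calls, since 0 of the 6 lists passed with an estimated correlation. A dependence of the array values on signal level, or one array, scramble UV-PAPC replicate 3, could account for part of them: 2 of the 6 lists stayed past the threshold after cyclic loess, and 2 without that array, and these numbers do not decide between the explanations. For heat shock genes the mean signals under both siRNAs were apart in untreated arrays and overlapped with UV-PAPC. An effect of lower OLR1 on the stress response stays open and was not tested apart from the siRNA. Further splits redrew the siRNA labels within each treatment after each gene's average siRNA effect was subtracted. Of 100 splits, the real split included, 13 gave at least 6 lists. The highest among the redrawn splits was 12, so chance is not excluded.

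The response of the genes responding to UV-PAPC differed between siRNAs by camera at the preset correlation, but not with an estimated one. The median difference was 0.0549 for genes that rose on average (0.259 with scramble and 0.31 with OLR1 siRNA). For genes that fell it was 0.0475 (-0.284 and -0.242). Both were shifts upward, so with OLR1 siRNA the median rise was larger and the median fall smaller. With an estimated correlation neither set passed (limma's camera p = 0.30 and 0.38), nor did either with limma's fry (p = 0.28 and 0.36). Of 100 such splits, the real split included, 25 and 29 gave a median difference as far from 0. The highest values among the redrawn splits were 0.0862 and 0.11, so chance is not excluded for either set. For single genes limma called 0 in the difference (1004 at an unadjusted p under 0.05), a count that all 100 splits reach by construction, so they say nothing about chance there.

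In the 4 pairwise comparisons 3 arrays against 3 make 10 splits, too few for a share under 0.05. For genes, 1 split in each comparison, the real one, gave as many: 1347, 1236, 1789 and 2302 genes with limma, against a highest of 0 among the other splits. For gene lists with the preset correlation the real split gave 12 lists and the highest other 10 for UV-PAPC with scramble siRNA, 16 and 11 with OLR1 siRNA, and 6 and 5 for OLR1 siRNA in untreated cells, each the 1 split with as many. For OLR1 siRNA with UV-PAPC it gave 5 and the highest other 8, with 7 splits giving as many. The median of the other splits was 6, 5, 4 and 5 lists. Each other split mixed arrays of both groups, and the group effect was not subtracted, so part of it remained. These list counts are therefore not those of arrays without a difference, and do not measure false calls. For genes the mixing also widens the spread within the redrawn groups, so the 0 among the other splits says little about chance.

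Table entries without a single gene name, which the comparisons leave out, also differed between groups. They were fitted together with all 33297 entries, and p was adjusted over all of these. Of 13837 such entries limma called 236 for UV-PAPC with scramble siRNA (132 rose, 104 fell), 283 with OLR1 siRNA (218 rose, 65 fell), 411 for OLR1 siRNA in untreated cells (182 rose, 229 fell) and 517 with UV-PAPC (294 rose, 223 fell). For the difference of responses limma called 0 of them. Limma called larger shares of the 18417 tested genes: 7.31%, 6.71%, 9.71% and 12.5% in the same order of pairwise comparisons. No explanation was tested for the entries without a single gene name.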

How the results depend on the processing

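Cyclic loess, the 4 arrays left out together and the arrays left out in turn for gene lists were chosen only after the results were seen; the other alternatives were planned. Over 14 main results 193 of 222 alternatives gave the same direction and side of the threshold (a count within 1.5 times), 8 no longer passed and 21 moved. The 85 named gene results kept direction and side of the threshold in all 1372 alternatives run. Of these, 80 were picked from the same data as the largest changes past the threshold, and the others were far from passing. Their stability is therefore no measure of that of the other called genes. Of 576 alternatives for 45 single list calls 465 were the same, 110 no longer passed and 1 turned direction. OLR1 was lower in every alternative run, by -0.95 to -1.37 in untreated and -1.21 to -1.56 in UV-PAPC cells with each array left out.

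With 4 arrays left out together the counts of genes were 752 for UV-PAPC with scramble siRNA, 1091 for OLR1 siRNA in untreated cells and 1161 with UV-PAPC, from fewer arrays; with OLR1 siRNA the UV-PAPC count was 881. With each array left out in turn, also fewer arrays, they ranged from 868 to 1126, 1101 to 1513 and 1267 to 2254, and from 865 to 1040 for UV-PAPC with OLR1 siRNA. The lowest were those without the first scramble untreated, the second OLR1 siRNA untreated and the first OLR1 siRNA UV-PAPC array. Without the second or the third scramble untreated array OLR1 siRNA in untreated cells gave 1113 and 1158, and without the third scramble UV-PAPC array OLR1 siRNA with UV-PAPC gave 1372. The other alternatives gave 1166 to 1842, 1013 to 1533, 1654 to 2295 and 1599 to 2839 genes in the order of the 4 pairwise comparisons, and 0 in the difference of responses by limma (1004 at an unadjusted p under 0.05), as in each array left out.

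With an estimated correlation 2, 3, 1, 0 and 0 lists passed in the 5 comparisons. Fry called 8 for OLR1 siRNA with UV-PAPC and 0 for the difference of responses, and cyclic loess 10 for OLR1 siRNA in untreated cells; the cause was not tested. With each array left out, lists numbered 11 to 15, 12 to 15, 5 to 9, 5 to 7 and, for the difference, 2 (without the first scramble untreated array) to 10 (without the first OLR1 siRNA untreated array), with 3 without the third scramble UV-PAPC and 3 without the first OLR1 siRNA UV-PAPC array. After cyclic loess ribosomal proteins turned direction for OLR1 siRNA with UV-PAPC, from a median of 0.104 to -0.00109 (camera adjusted p = 0.779, range over the alternatives 0.000257 to 0.779); the cause was not tested.

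The response size difference no longer passed for rising and falling genes with an estimated correlation (0.0549, limma's camera p = 0.304, and 0.0475, p = 0.384) or among the brighter genes (0.0568, p = 0.162, and 0.0508, p = 0.313), nor for falling genes after cyclic loess (0.0264, p = 0.119); the cause was not tested. With array weights it was 0.0261 and 0.0296 and passed. With each array left out it ranged from 0.014 to 0.0844 and from 0.0175 to 0.079, lowest without the third scramble UV-PAPC array, where rising genes no longer passed camera and falling genes did. For falling genes it also did not pass camera without the third OLR1 siRNA untreated (0.0229) or the third OLR1 siRNA UV-PAPC array (0.0233). Over the alternatives camera p ranged from 2.24e-07 to 0.304 and from 7.78e-08 to 0.384.

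No general pairing of arrays by replicate number was seen. Deviations from group means correlated across genes, which are not independent replicates, at -0.221 to 0.263 for arrays of the same number and -0.26 to 0.266 for others. Of 12 arrays 4 correlated best with their own number. Arrays numbered 1 correlated with each other at 0.0232 to 0.179, and those of the other numbers at values of both signs, so a shared batch is not excluded. OLR1 signal was highest in the array numbered 1 of each group, so its SE may include a shared replicate effect. With the number as a block limma called 1309, 1220, 1756, 2309 and 0 genes, and the list counts stayed at 12, 16, 6, 5 and 6. Array signal lies over a background that the table does not give, so folds of dim genes, OLR1 in the siRNA arrays among them, are limited by it.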

Other observations

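The gene families, and the tests of the patterns in the last 2 paragraphs, were chosen only after the data were seen.

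The histone genes that passed the threshold moved the same way as those of the G2/M list in each of the 4 pairwise comparisons. Of 63 histone genes 23 rose with OLR1 siRNA in untreated cells, H3C1 by 0.52, H2AC14 by 0.51 and H2AC4 by 0.49 among them (median 0.25, camera adjusted p = 8.83e-12; adjusted p = 0.99 with an estimated correlation), and 3 with UV-PAPC (median 0.14, camera adjusted p = 0.00787; adjusted p = 0.76 with an estimated correlation). With UV-PAPC 22 fell under OLR1 siRNA, including the linker histone H1-3 (-1.10), H2BC14 (-0.65) and H3C12 (-0.57), and 8 under scramble siRNA. Those medians were -0.23 and -0.14 (camera adjusted p = 1.22e-14 and 0.000134; adjusted p = 0.89 and 0.99 with an estimated correlation). The difference of responses had a median of -0.13 (camera adjusted p = 2.87e-05; adjusted p = 0.90 with an estimated correlation) and 0 members past the threshold with limma, while those of the G2/M and G1/S lists were -0.03 and 0.06. Histone paralogs are near-identical, so single members are uncertain.

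Members of other families also passed the threshold with OLR1 siRNA in UV-PAPC cells, where camera called 24 families higher and 8 lower, 0 of them with an estimated correlation. Of 11 MCM genes, most of which encode the replicative helicase and some of which are in the G1/S list, 7 rose, such as MCM6 (0.45), MCM10 (0.42) and MCM2 (0.35). Of 23 nucleoporin genes 11 rose, among them NUP37 (0.44), NUP160 (0.43) and NUP107 (0.41), and of 28 Mediator genes 12 rose, such as MED11 (0.53), MED20 (0.52) and MED24 (0.50). Camera gave adjusted p = 0.00024, 0.00024 and 0.000681, and adjusted p = 0.71 for each with an estimated correlation. The nucleoporin median of 0.22 was 0.13 after repeated quantile normalization and 0.11 after cyclic loess. Among the 8 lower families 5 of 44 COL, 4 of 23 CLDN, 4 of 68 KRTAP, 3 of 8 LHX, 2 of 13 NKX, 1 of 18 SYT, 1 of 19 SOX and 0 of 22 FGF genes fell. After cyclic loess some medians shrank, from 0.101 to 0.00366 for RPL, 0.096 to 0.0112 for EIF and -0.078 to -0.0335 for KRTAP genes. Others changed little, such as MED (0.213 and 0.198), or moved further from 0, such as NKX (-0.157 and -0.193). The cause was not tested. Of 314 families of at least 8 genes with a shared symbol stem, camera called 7, 15, 2, 32 and 4 in the 5 comparisons, and with an estimated correlation 1, 0, 0, 0 and 0. That 1 had the stem HSP, with UV-PAPC under scramble siRNA, where 7 of 14 rose (adjusted p = 0.039 with an estimated correlation). Stems ended before the first digit, so it holds HSP90 symbols and not the HSPA genes. The latter formed a family of 12 (camera adjusted p = 0.17 with an estimated correlation). Near-identical members may share probe signal, so the 14 may not be separate measurements. None of the named families turned direction after centring, repeated quantile normalization or cyclic loess.

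The remaining lists did not pass camera in any comparison. For UV-PAPC with scramble siRNA, with OLR1 siRNA, and for OLR1 siRNA in untreated and UV-PAPC cells, the adjusted p were 0.75, 0.536, 0.825 and 0.75 for LXR targets, 0.579, 0.249, 0.881 and 0.602 for PPAR targets, 0.849, 0.467, 0.881 and 0.357 for apoptosis regulators, and 0.957, 0.692, 0.825 and 0.465 for aryl hydrocarbon receptor targets. They were 0.75, 0.45, 0.881 and 0.861 for eicosanoid enzymes, 0.75, 0.467, 0.114 and 0.353 for lipid droplet genes, 0.34, 0.586, 0.114 and 0.327 for matrix genes, and 0.538, 0.736, 0.587 and 0.719 for p53 targets. Fry, which does not compare a set with other genes, gave matrix genes adjusted p = 0.02 with UV-PAPC under scramble siRNA, and matrix and lipid droplet genes 0.0185 each with OLR1 siRNA in untreated cells, all lower on balance.

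Among called genes 36.5% rose with UV-PAPC under scramble siRNA and 51.6% under OLR1 siRNA, a gap of 15.1 percentage points. A candidate explanation is one array, scramble UV-PAPC replicate 3, without which the gap was 3.66 points (47.4% and 51.0%). That array lay farthest out on the first component of the deviations from group means, which held 26.1% of their variance and whose gene loadings correlated with mean signal across genes, which are not independent replicates, at -0.337. A dependence of the array values on signal level is not decided, with a gap of 9.41 points after cyclic loess and 6.73 after repeated quantile normalization. A difference between the siRNAs in the response itself stays open.

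Several genes fell at least as far as OLR1 with OLR1 siRNA: 8 in untreated cells and 2 with UV-PAPC, LRRC58 and ATP6V0E2, the 2 in both. These counts are uncertain, since with each array left out in turn OLR1 ranged from -1.365 to -0.946 and from -1.56 to -1.21. A candidate explanation is the siRNA acting on transcripts other than that of OLR1: falls made up 67.2% of called genes changed 1.5-fold or more and 42.8% of those changed less in untreated cells (odds ratio 2.73, Fisher's exact test across genes, p = 1.15e-10), and 59.8% to 70.4% of the former after 3 rescalings. With UV-PAPC falls were 46.6% of called genes changed 1.5-fold or more (68 falls, 78 rises) and 35.8% of those changed less. The odds ratio was 1.56 (Fisher's exact test, p = 0.00997), and 1.60 to 2.11 after the rescalings. The former share, 39.3% to 55.8% after the rescalings, was a majority only in some. Loss of OLR1 could also lower genes, so these shares do not decide the explanation in either treatment. Genes are not independent, the 1.5-fold limit was chosen after the counts were seen, and at 2-fold the rises and falls numbered 6 and 27 in untreated cells and 9 and 9 with UV-PAPC. OLR1 signal near the floor of the arrays may also shorten its measured fall. Its median percentile in the OLR1 siRNA arrays was 20.9, but a rank among other probe sets does not give the distance from background. Loss of OLR1 itself could also lower these 2 genes, and cannot be told apart here, with 1 siRNA label and no rescue.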
